A study of Homo sapiens with 18 samples.

How the data were processed

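RNA from 18 samples of sorted human Tregs was measured on Affymetrix Human Gene 1.0 ST arrays. Naive, memory and CD161+ Tregs of 3 donors were each used fresh and after 4 h with CD3/CD28 beads. Per the labels, 200000 cells were sorted into Trizol LS, RNA was purified with RNeasy, cDNA was amplified with the Ovation PicoSL WTA V2 kit and labelled with the Encore Biotin kit. The deposited table held log2 intensities that the authors summarised and normalized with RMA, and the labels also name Partek and GenomeStudio. The labels state neither versions, a genome build, a filter nor the base of the logarithm, and base 2 was taken because RMA returns it and the range of 1.59 to 14.0 has that form. The table had 28869 probe sets and no missing value. Array medians lay between 4.89 and 5.14, and correlations between arrays between 0.838 and 0.986. The number of arrays limits the precision.

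Of the probe sets, 19229 had 1 gene symbol, 1732 had several and 7908 had none. Only those with 1 symbol were used, and 24 of the Y chromosome or of XIST and TSIX were removed before any fit. Where a gene had several probe sets (672 genes), the one with the highest mean over all arrays stood for it, which left 18354 genes. No filter on dim probe sets was applied. No genome build was given, so genes are named by symbol without positions. Background was measured as the array's median over 336 olfactory receptor genes. A group mean within the 90th percentile of these genes in its group is called near background, a limit chosen after seeing the data.

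Each gene was fitted with limma 3.58.1 in R 4.3.3, with a mean per group over all 18 arrays and 1 shared spread. Contrasts were tested two-sided with the moderated test of limma at default settings, and p-values were adjusted by Benjamini-Hochberg over all 18354 genes within a contrast. Genes with an adjusted p under 0.05 are called. The 11 contrasts were the 3 pairs of populations in fresh cells, the same pairs in activated cells, activation in each population, and the difference of the activation response between CD161+ and memory and between memory and naive Tregs. Values were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and drawn with matplotlib 3.10.9. These choices, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined.

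The labels number the donors 1 to 3 in every group and state no paired test, so the contrasts have no donor term and a fit with the donor number as a block is an alternative. The numbering was checked on the residuals of the group means. Arrays of the same donor in different groups had a mean residual correlation of 0.107 over 45 pairs, against −0.05 over 90 pairs of different donors, and 17 of 18 arrays correlated best with their own donor number. These pairs share arrays and are not independent. The blocked value stands beside a result where the block changes the call.

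A total of 29 gene lists with 308 distinct genes were tested, of which 285 were measured. They were Treg core, naive T cell, memory and effector T cell, HLA class II, type 17, innate-like T cell, retinoic acid, gut homing, skin homing, tissue repair, type 1, type 2, follicular helper, cytotoxicity, suppressive mediators, immediate early, NF-kB targets, induced cytokines, costimulatory receptors, ribosome biogenesis, glycolysis, cell division, interferon response and heat shock. Markers of CD8 T cells, B cells, monocytes, NK cells, and platelets and red cells covered other cells the gate could hold. Each list was tested with camera of limma at a preset correlation of 0.01, again with an estimated correlation, and with fry, and adjusted by Benjamini-Hochberg over the lists within a contrast. Counts of members are given over all genes tested and adjusted over the list alone. The other 23 genes were not analysed here.

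Named genes followed a rule with 3 parts. Part (a) took the 5 largest rises and the 5 largest falls among genes called and moving the same way in all 3 donors. It passed over symbols without an official gene name, small RNAs, pseudogenes and receptor segments. Part (b) took KLRB1, FOXP3, IL2RA and CTLA4 between populations, and IL2RA, CD69, IL2, IL10 and FOXP3 for activation. Part (c) took up to 4 members of each list with the smallest p, and outside the contrasts of CD161+ with memory Tregs and of activation only of lists that passed.

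The alternatives fixed at that time were the donor block, quantile normalization or median centring of the deposited values, removal of probe sets with a mean below the median, the mean of a gene's probe sets, limma's trend and robust options, array weights, a fit on the contrast's groups alone, an added 1.5-fold minimum, an adjusted p under 0.1, each donor left out, each array left out, and for lists the estimated correlation. Another 3 were added after seeing the data: array background as a covariate, leaving out the pair of arrays with the highest background, and leaving KLRB1, the gene of the sort marker, out of the lists that hold it. Recovery was tested on simulated data with the same layout, with 50 changed genes for each of 4 sizes.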

Results

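RNA of human regulatory T cells (Tregs) was measured on 18 Affymetrix Human Gene 1.0 ST arrays. Naive, memory and CD161+ Tregs of 3 donors were lysed either fresh after sorting or after 4 h of activation with CD3/CD28 beads, which gave 6 groups of 3 arrays with 1 array per donor in each. CD161 is a surface receptor encoded by KLRB1 that is known from natural killer cells and type 17 T cells. The values were deposited log2 intensities. Fresh arrays had a higher background: the median of 336 olfactory receptor genes, which T cells are not known to use, was 3.55 ± 0.12 (SD, n = 3) in fresh naive, 3.47 ± 0.05 in fresh memory and 3.38 ± 0.05 in fresh CD161+ Tregs, against 3.21 ± 0.07, 3.21 ± 0.05 and 3.26 ± 0.01 after activation. Differences below are log2 with the standard error (SE) of the fit and n = 3 per group. Named genes past the threshold moved the same way in all 3 donors except where stated. Called genes are flagged near background where the lower mean lay within the 90th percentile of its group's olfactory receptor genes (4.18 to 4.64). Their unshifted difference is a lower bound in size. Differences of responses that rest on such levels are bounded in neither direction and were not all checked. List calls printed with 1 adjusted p under 0.05, from camera, also held with an estimated correlation between genes.

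**Figure D1:**
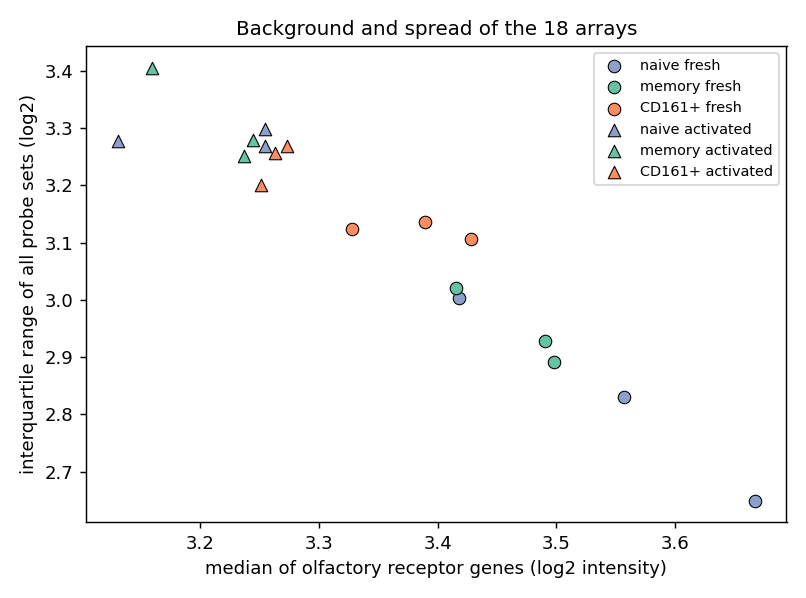
Each point is 1 of the 18 arrays, with the median log2 intensity of 336 olfactory receptor genes on the x axis and the interquartile range of all probe sets (log2) on the y axis. Circles are fresh and triangles activated samples, and 2 of the 3 fresh naive arrays lie farthest to the right, in a group with a mean of 3.55.

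Fresh CD161+ and memory Tregs were compared to find what sets the CD161+ cells apart at rest. KLRB1, the marker the cells were sorted on, was 25.4-fold higher in CD161+ cells (4.67 ± 0.53, adjusted p = 6.94e-04). CCR9, the receptor that guides lymphocytes to the small intestine, was higher by 2.20 ± 0.30, adjusted p = 0.0044. GPR65, a proton-sensing receptor, was higher by 2.20 ± 0.48, adjusted p = 0.0458, as were DNTTIP2 (2.08 ± 0.44, adjusted p = 0.0433) and RBMS1 (2.38 ± 0.47, adjusted p = 0.0305), although only 1 of the 2 RBMS1 probe sets moved that way. IKZF2, which encodes the Treg transcription factor Helios, was lower in CD161+ cells (−2.21 ± 0.35, adjusted p = 0.0129). MTX3 (−2.79 ± 0.35, adjusted p = 0.0021) and the urea transporter gene SLC14A1 (−2.05 ± 0.39, adjusted p = 0.0267) were lower too. PARP15 (−1.86 ± 0.29, adjusted p = 0.0109) and TTN (−1.85 ± 0.36, adjusted p = 0.0278) were lower as well. FOXP3, the master regulator of Tregs, did not pass (−0.51 ± 0.19, adjusted p = 0.207), nor did CTLA4 (−0.52 ± 0.22, adjusted p = 0.282) or the interleukin 2 receptor gene IL2RA (−0.11 ± 0.22, adjusted p = 0.872).

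Treg core genes gave 1 of 15 lower, 1 higher and 4 lower adjusted over the list alone (adjusted p = 0.0045, 0.236 with an estimated correlation), with RTKN2 at −1.37 ± 0.38, adjusted p = 0.0986. Type 17 genes leaned the other way: 1 of 16 higher, 7 higher and 1 lower adjusted over the list alone (adjusted p = 4.21e-04, 0.230 with an estimated correlation). KLRB1, on which the cells were sorted, was the 1 call. Without KLRB1, 0 of 15 passed in limma and 6 were higher and 1 lower at an unadjusted p under 0.05 (adjusted p = 0.0040, 0.236 with an estimated correlation). Gut homing receptors gave 1 of 8 higher, 4 higher adjusted over the list alone (adjusted p = 0.0012, 0.236 with an estimated correlation), with CCR2 at 2.12 ± 0.47, adjusted p = 0.0527. The follicular helper list held POU2AF1, a transcriptional coactivator, which was higher by 1.19 ± 0.20, adjusted p = 0.0166, with 1 of 6 higher, 2 higher adjusted over the list alone (adjusted p = 0.0723, 0.236 with an estimated correlation). Cell division genes tended to higher values in CD161+ cells: 0 of 13 past the threshold, 7 higher adjusted over the list alone and 7 higher at an unadjusted p under 0.05 (adjusted p = 3.01e-04, 0.230 with an estimated correlation, fry adjusted p = 0.0143). BUB1 (1.06 ± 0.24, adjusted p = 0.0531) and CCNB1 (0.92 ± 0.23, adjusted p = 0.0716) led, from memory levels near background. Glycolysis followed: 0 of 15 past the threshold, 2 higher adjusted over the list alone and 6 higher at an unadjusted p under 0.05 (adjusted p = 9.87e-04, 0.232 with an estimated correlation, fry adjusted p = 0.0143). Ribosome biogenesis gave 0 of 12 past the threshold, 2 higher adjusted over the list alone and 3 higher at an unadjusted p under 0.05 (adjusted p = 0.0020, 0.259 with an estimated correlation, fry adjusted p = 0.0424). Heat shock had 0 of 7 past the threshold, 1 higher adjusted over the list alone and 3 higher at an unadjusted p under 0.05 (adjusted p = 0.0238, 0.498 with an estimated correlation, fry adjusted p = 0.171). Memory and effector genes gave 0 of 16 past the threshold, 2 higher adjusted over the list alone and 2 higher at an unadjusted p under 0.05 (adjusted p = 0.0388, 0.645 with an estimated correlation, fry adjusted p = 0.310). Memory and effector, cell division and heat shock lists lost calls without dim probe sets (adjusted p = 0.323, 0.137 and 0.137).

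Lists that did not pass camera in fresh cells were naive T cell (adjusted p = 0.102), interferon response (0.0723), cytotoxicity (0.367), tissue repair factors (0.406), type 2 (0.463), type 1 (0.833) and skin homing (0.921). The same held for HLA class II (adjusted p = 0.892), NF-kB targets (0.892), costimulatory receptors (0.921), immediate early genes, induced cytokines and suppressive mediators (each 1.00). The innate-like list held KLRB1 as its 1 passing gene and had a median of −0.12, a mean of 0.34 and a camera direction of down (adjusted p = 1.00). Retinoic acid genes likewise had a median of −0.12 and a mean of 0.05 with adjusted p = 0.892. Median, mean and camera direction also differed in sign, near 0, for suppressive mediators, immediate early genes, NF-kB targets, costimulatory receptors and the natural killer cell markers. Monocyte markers stood higher in CD161+ samples without passing, with S100A8 at 2.00 ± 1.55, adjusted p = 0.593 and LYZ at 1.76 ± 1.47, adjusted p = 0.627 (list adjusted p = 0.128, and 0.0199 with the donor as a block). Markers of CD8 T cells (0.892), B cells (0.892), natural killer cells (0.842), and platelets and red cells (0.367) did not pass.

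In all, limma called 116 of 18354 genes between fresh CD161+ and memory Tregs, 70 higher and 46 lower, or 114 and 32 after median centring. The number was 189 with the donor as a block, 1 when only these 6 arrays were fitted, 195 with array background as a covariate (80 higher and 115 lower, the other way round), and 555 without the highest-background pair of arrays. It was 40, 3 and 237 without donor 1, 2 and 3, and leaving out single arrays gave 18 without fresh CD161+ replicate 2 or 3 and 16, 26 and 691 without fresh memory replicate 1, 2 and 3. Of the 11 named genes that passed, 8, 10 and 2 no longer did without donor 1, 2 and 3, and KLRB1 alone passed in each case.

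**Figure D2:**
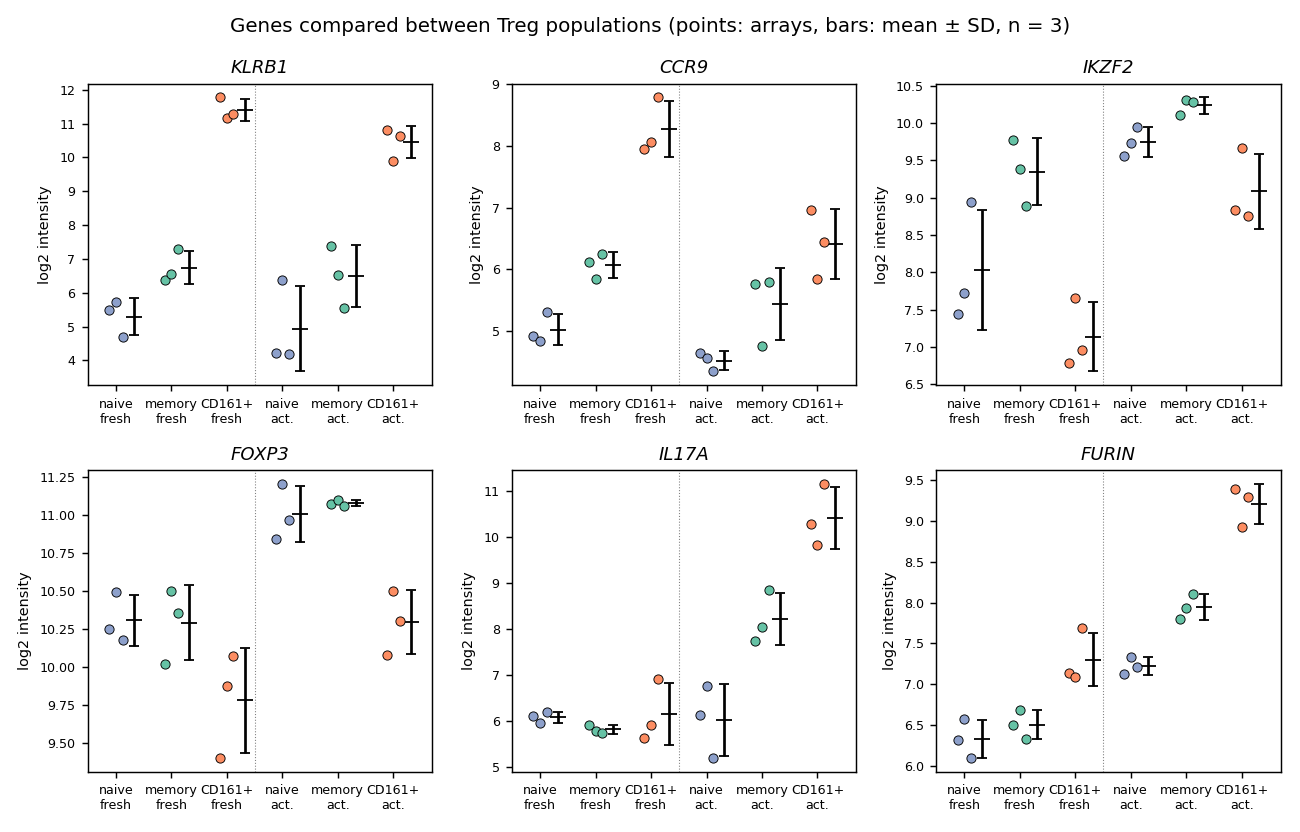
Log2 intensity (y axis) of 6 genes in the 6 groups (x axis), with 1 point per array and bars for the mean ± SD (n = 3). KLRB1 had a mean of 11.40 in fresh CD161+ Tregs against 6.74 in fresh memory Tregs, and IL17A a mean of 10.41 in activated CD161+ against 8.21 in activated memory Tregs.

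After activation, CD161+ and memory Tregs were compared for the same purpose. KLRB1 was 15.7-fold higher in CD161+ cells (3.97 ± 0.53, adjusted p = 0.0132). HRH4, a histamine receptor gene, was higher by 2.24 ± 0.31, adjusted p = 0.0132. PTPN13, a tyrosine phosphatase gene, was higher by 1.69 ± 0.25, adjusted p = 0.0188 and FURIN, the protease that matures TGF-beta, by 1.26 ± 0.19, adjusted p = 0.0189; with the donor as a block their adjusted p were 0.0565 and 0.0565. FOXP3 (−0.78 ± 0.19, adjusted p = 0.432), CTLA4 (0.18 ± 0.22, adjusted p = 1.00) and IL2RA (−0.02 ± 0.22, adjusted p = 1.00) did not pass. PTPN13 had a lower mean of 3.71, near background.

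Type 17 genes as a group were higher in activated CD161+ Tregs: 2 of 16 higher, 10 higher adjusted over the list alone (adjusted p = 3.57e-19). KLRB1 and PTPN13 were the 2 calls. Without KLRB1, 1 of 15 was higher (adjusted p = 2.60e-15). The cytokine gene IL17A of that list was at 2.20 ± 0.40, adjusted p = 0.119 and IL17F at 1.51 ± 0.37, adjusted p = 0.450, higher in all 3 donors but short of the threshold singly. Treg core genes were lower as a group: 0 of 15 past the threshold, 7 lower adjusted over the list alone and 7 lower at an unadjusted p under 0.05 (adjusted p = 6.14e-11, fry adjusted p = 0.0219). RTKN2 (−1.86 ± 0.38, adjusted p = 0.236) and LRRC32, which encodes the TGF-beta anchor GARP (−1.44 ± 0.31, adjusted p = 0.331), led it. Induced cytokines shared IL17A and IL17F with the type 17 list, with 0 of 22 past the threshold, 8 higher adjusted over the list alone and 10 higher at an unadjusted p under 0.05 (adjusted p = 6.14e-11, 0.0710 with an estimated correlation, fry adjusted p = 0.118). Gut homing receptors gave 0 of 8 past the threshold, 5 higher adjusted over the list alone and 5 higher at an unadjusted p under 0.05 (adjusted p = 1.10e-04, 0.0971 with an estimated correlation, fry adjusted p = 0.150). Naive T cell genes had 0 of 12 past the threshold, 2 lower adjusted over the list alone and 3 lower at an unadjusted p under 0.05 (adjusted p = 4.95e-04, 0.0971 with an estimated correlation, fry adjusted p = 0.254). Innate-like genes held KLRB1: 1 of 12 higher, 2 higher adjusted over the list alone (adjusted p = 0.0017, 0.0971 with an estimated correlation). Without KLRB1, 0 of 11 passed in limma and 2 were higher at an unadjusted p under 0.05 (adjusted p = 0.0911, 0.419 with an estimated correlation). Tissue repair factors held FURIN: 1 of 12 higher, 1 higher adjusted over the list alone (adjusted p = 0.0093, 0.236 with an estimated correlation). The follicular helper list gave 0 of 6 past the threshold, 2 higher adjusted over the list alone and 2 higher at an unadjusted p under 0.05 (adjusted p = 0.0189, 0.0971 with an estimated correlation, fry adjusted p = 0.149). The type 2 list had adjusted p = 0.0582, and 0.0112 with the donor as a block, with IL4 at 1.21 ± 0.55, adjusted p = 1.00. Cell division (adjusted p = 0.0705), glycolysis (0.228), ribosome biogenesis and heat shock (each 0.801) did not pass, nor did memory and effector genes (0.268). Median, mean and test differed in sign, near 0, for skin homing, suppressive mediators, NF-kB targets and heat shock. Monocyte markers were at 1.22 ± 1.47, adjusted p = 1.00 for LYZ (list adjusted p = 0.801).

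KLRB1, HRH4, PTPN13 and FURIN were the 4 genes limma called, all higher, while 531 genes had an unadjusted p under 0.05. The count was 2 in a fit of these 6 arrays alone, 2 with the donor as a block, 2 without dim probe sets and 45 with array weights. It came to 0, 1 and 0 without donor 1, 2 and 3 (unadjusted 574 and 366 for the counts of 0), and to 0 and 1 without activated CD161+ replicate 1 and 3 and 1 and 0 without activated memory replicate 1 and 3 (unadjusted 366 and 362).

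**Figure D3:**
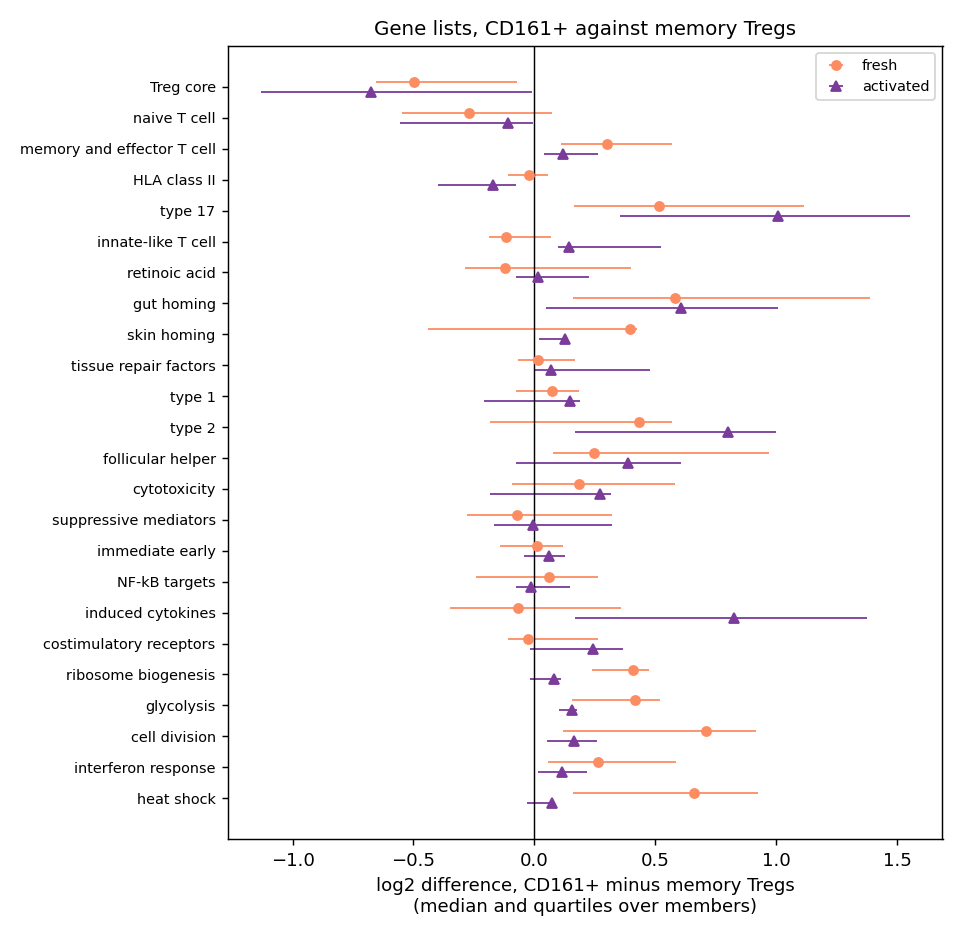
Median log2 difference between CD161+ and memory Tregs (x axis) over the measured members of each gene list (y axis), with bars for the quartiles. Circles are fresh and triangles activated cells, and the type 17 list had medians of 0.52 and 1.01 against −0.50 and −0.67 for Treg core genes.

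Fresh CD161+ Tregs were also compared with fresh naive Tregs. KLRB1 was 69.1-fold higher (6.11 ± 0.53, adjusted p = 7.03e-06). The chemokine receptor genes CCR4 (4.21 ± 0.47, adjusted p = 4.37e-05) and CCR2 (4.19 ± 0.47, adjusted p = 5.20e-05) were higher, as were PRDM1, which encodes the effector regulator Blimp-1 (4.07 ± 0.38, adjusted p = 1.42e-05), and ANXA1 (3.91 ± 0.74, adjusted p = 0.0023). UBE2E2 (−3.42 ± 0.32, adjusted p = 1.42e-05), FCER1G (−3.12 ± 0.69, adjusted p = 0.0067) and the BMP antagonist gene NOG (−3.04 ± 0.33, adjusted p = 4.19e-05) were lower. TCEA3 (−2.93 ± 0.32, adjusted p = 4.37e-05) and VNN2 (−2.80 ± 0.39, adjusted p = 2.29e-04) were lower as well. FOXP3 did not pass (−0.52 ± 0.19, adjusted p = 0.0693, and 0.0291 with the donor as a block), nor did IL2RA (0.55 ± 0.22, adjusted p = 0.101) or CTLA4 (0.32 ± 0.22, adjusted p = 0.353). UBE2E2 and VNN2 had lower means of 4.31 and 4.16, near background.

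Memory and effector genes made up the clearest group: 14 of 16 higher, 15 higher adjusted over the list alone (adjusted p = 9.58e-18). Gut homing receptors followed, with 6 of 8 higher, 6 higher adjusted over the list alone (adjusted p = 1.40e-07), with CCR9 higher by 3.25 ± 0.30 and the integrin gene ITGA4 by 2.19 ± 0.21. Skin homing gave 3 of 5 higher, 4 higher adjusted over the list alone (adjusted p = 1.17e-04). Type 17 genes included CCR6 (2.89 ± 0.33) and AHR (2.10 ± 0.35), with 8 of 16 higher, 9 higher adjusted over the list alone (adjusted p = 1.57e-06). Without KLRB1, 7 of 15 were higher (adjusted p = 2.57e-05). Cell division gave 7 of 13 higher, 9 higher adjusted over the list alone (adjusted p = 1.09e-05), with TYMS higher by 2.62 ± 0.48 and MCM4 by 1.26 ± 0.18. Naive T cell genes ran opposite, with 1 of 12 higher and 6 lower, 1 higher and 7 lower adjusted over the list alone (adjusted p = 0.0055, 0.161 with an estimated correlation), with BACH2 at −1.93 ± 0.26 and the lymph node receptor gene CCR7 at −0.81 ± 0.19. Type 1 genes gave 5 of 9 higher, 6 higher adjusted over the list alone (adjusted p = 0.0055, 0.161 with an estimated correlation), with GZMK higher by 3.68 ± 0.58. Type 2 genes gave 3 of 9 higher, 3 higher adjusted over the list alone (adjusted p = 0.0062, 0.249 with an estimated correlation), with GATA3 higher by 1.64 ± 0.23. Suppressive mediators gave 5 of 14 higher and 1 lower, 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.0154, 0.161 with an estimated correlation). Costimulatory receptors had 3 of 13 higher, 3 higher adjusted over the list alone (adjusted p = 0.0173, 0.0712 with an estimated correlation). Glycolysis gave 5 of 15 higher, 5 higher adjusted over the list alone (adjusted p = 0.0055, 0.161 with an estimated correlation). Interferon response had 4 of 14 higher, 7 higher adjusted over the list alone (adjusted p = 0.0023, 0.116 with an estimated correlation). Heat shock had 4 of 7 higher, 4 higher and 1 lower adjusted over the list alone (adjusted p = 0.0420, 0.400 with an estimated correlation). The heat shock test gave adjusted p = 0.0524 with the donor as a block. Median and test differed in sign for innate-like genes, induced cytokines and monocyte markers, which did not pass. TYMS had a lower mean of 4.30, near background. Costimulatory receptors, glycolysis, cell division, interferon response and heat shock lists lost calls without dim probe sets (adjusted p = 0.221, 0.161, 0.0589, 0.172 and 0.269).

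A total of 2677 genes were called between fresh CD161+ and naive Tregs, 1825 higher and 852 lower, or 2015 and 494 after median centring. Fitted on these 6 arrays alone the count was 584, with array background as a covariate 577 and without the highest-background pair of arrays, which leaves 1 fresh naive array, 635; the covariate ended 20 of the 50 named calls. It was 1122, 527 and 2754 without donor 1, 2 and 3, and single arrays gave 1559 and 1738 without fresh CD161+ replicate 2 and 3 and 1505 and 4573 without fresh naive replicate 1 and 3.

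Memory and naive Tregs, both fresh, were compared in turn. CCR4 (3.78 ± 0.47, adjusted p = 2.09e-04), NIBAN1 (3.72 ± 0.34, adjusted p = 4.23e-05) and the granzyme gene GZMK (3.50 ± 0.58, adjusted p = 0.0016) were most increased in memory cells. CD84 (3.42 ± 0.27, adjusted p = 7.52e-06) and PRDM1 (3.31 ± 0.38, adjusted p = 1.12e-04) followed. UBE2E2 (−2.61 ± 0.32, adjusted p = 1.61e-04), FCER1G (−2.34 ± 0.69, adjusted p = 0.0443) and APBA2 (−2.32 ± 0.33, adjusted p = 5.59e-04) were lower. AIF1 (−2.30 ± 0.35, adjusted p = 9.57e-04) and LAPTM4B (−2.30 ± 0.30, adjusted p = 2.71e-04) were lower as well. CTLA4, an inhibitory receptor gene, was higher by 0.83 ± 0.22, adjusted p = 0.0278. KLRB1 (1.44 ± 0.53, adjusted p = 0.0974), FOXP3 (−0.02 ± 0.19, adjusted p = 0.969) and IL2RA (0.66 ± 0.22, adjusted p = 0.0708) did not pass.

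Memory and effector genes gave 12 of 16 higher, 13 higher adjusted over the list alone (adjusted p = 3.60e-17), including AHNAK (2.04 ± 0.21) and the death receptor gene FAS (1.94 ± 0.25). Skin homing receptors counted CCR8 (2.34 ± 0.37), with 4 of 5 higher, 4 higher adjusted over the list alone (adjusted p = 4.18e-05). Gut homing receptors counted GPR15 (2.06 ± 0.38), with 6 of 8 higher, 6 higher adjusted over the list alone (adjusted p = 9.69e-06, 0.0831 with an estimated correlation). Treg core genes counted ENTPD1, which encodes CD39 (2.49 ± 0.44), and IKZF2 (1.31 ± 0.35, higher in 2 of 3 donors), with 4 of 15 higher, 7 higher adjusted over the list alone (adjusted p = 1.76e-04, 0.0939 with an estimated correlation). Type 17 genes counted RORA (1.44 ± 0.18) and AHR (1.93 ± 0.35), with 4 of 16 higher, 5 higher adjusted over the list alone (adjusted p = 0.0088, 0.215 with an estimated correlation). Innate-like genes gave 3 of 12 higher, 4 higher adjusted over the list alone (adjusted p = 0.0277, 0.255 with an estimated correlation). Type 1 genes had 4 of 9 higher, 5 higher adjusted over the list alone (adjusted p = 0.0088, 0.215 with an estimated correlation). Type 2 genes had 3 of 9 higher, 3 higher adjusted over the list alone (adjusted p = 0.0238, 0.371 with an estimated correlation). Suppressive mediators gave 4 of 14 higher, 4 higher and 1 lower adjusted over the list alone (adjusted p = 0.0088, 0.136 with an estimated correlation). Costimulatory receptors had 3 of 13 higher, 5 higher adjusted over the list alone (adjusted p = 0.0105, 0.0806 with an estimated correlation). HLA class II gave 0 of 7 past the threshold, 2 higher adjusted over the list alone and 2 higher at an unadjusted p under 0.05 (adjusted p = 0.0416, 0.379 with an estimated correlation, fry adjusted p = 0.121). The interferon list missed the threshold with adjusted p = 0.0535, and 0.0415 with the donor as a block. Signs of median, mean and test differed for follicular helper, cytotoxicity, NF-kB, induced cytokine and glycolysis genes, none of which passed. ENTPD1 and GPR15 had lower means of 4.43 and 4.28, near background. HLA class II, innate-like and costimulatory receptors lists lost calls without dim probe sets (adjusted p = 0.192, 0.0577 and 0.0577).

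Between fresh memory and naive Tregs 1675 genes passed, 1088 higher and 587 lower. The count was 58 in a fit of these 6 arrays alone, 950 with the background covariate and 247 without the highest-background pair, which leaves 1 fresh naive array and ended 19 of 35 named calls. It was 298, 222 and 1730 without donor 1, 2 and 3, and 856, 1026 and 3351 without fresh naive replicate 1, 2 and 3.

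Activated CD161+ Tregs were compared with activated naive Tregs as well. IL5 (5.55 ± 0.60, adjusted p = 3.07e-05) and IL13 (4.41 ± 0.67, adjusted p = 9.72e-04), cytokines of type 2 responses, were higher, as were KLRB1 (5.52 ± 0.53, adjusted p = 9.67e-06), CCR2 (4.70 ± 0.47, adjusted p = 1.56e-05) and CCR6 (4.65 ± 0.33, adjusted p = 1.07e-06). The focal adhesion kinase gene PTK2 (−3.44 ± 0.27, adjusted p = 1.67e-06), SCML1 (−3.20 ± 0.51, adjusted p = 0.0015) and CLDN1 (−3.12 ± 0.24, adjusted p = 1.47e-06) were lower. IGF1R (−2.85 ± 0.45, adjusted p = 0.0012) and HOMER1 (−2.85 ± 0.36, adjusted p = 1.84e-04) were lower as well. FOXP3 was at −0.71 ± 0.19, adjusted p = 0.0553 (0.0170 with the donor as a block), CTLA4 at 0.83 ± 0.22, adjusted p = 0.0604 (0.0312 with the block) and IL2RA at 0.53 ± 0.22, adjusted p = 0.370. IL5, CCR2, PTK2 and CLDN1 had lower means of 3.34, 3.71, 3.43 and 4.22, near background.

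Type 17 genes were the group with the smallest p: 12 of 16 higher, 13 higher adjusted over the list alone (adjusted p = 4.49e-36). Without KLRB1, 11 of 15 were higher (adjusted p = 1.67e-32). IL17A was 21-fold higher (4.39 ± 0.40) and MAF higher by 4.31 ± 0.33. Memory and effector genes gave 10 of 16 higher, 14 higher adjusted over the list alone (adjusted p = 6.37e-28). Induced cytokines, which overlap with the type 17 and type 2 lists, gave 11 of 22 higher, 13 higher adjusted over the list alone (adjusted p = 1.04e-17), with IL21 higher by 3.43 ± 0.34. Gut homing gave 6 of 8 higher, 6 higher adjusted over the list alone (adjusted p = 1.04e-17). Skin homing had 3 of 5 higher, 3 higher adjusted over the list alone (adjusted p = 2.58e-06). Type 2 gave 6 of 9 higher, 7 higher adjusted over the list alone (adjusted p = 2.49e-16), with IL4 higher by 3.47 ± 0.55. Suppressive mediators gave 4 of 14 higher, 8 higher adjusted over the list alone (adjusted p = 1.30e-09), with IL10 higher by 3.96 ± 0.43 and LAG3 by 1.90 ± 0.27. Costimulatory receptors gave 3 of 13 higher and 1 lower, 11 higher and 2 lower adjusted over the list alone (adjusted p = 2.79e-07), with TNFRSF4 higher by 1.16 ± 0.24 and TNFRSF9 at −1.06 ± 0.24. Type 1 gave 3 of 9 higher, 7 higher adjusted over the list alone (adjusted p = 3.66e-07), with IFNG higher by 2.32 ± 0.54 and CCL5 by 2.56 ± 0.65, adjusted p = 0.0459 (2 of 3 donors, 0.0620 with the donor as a block). Immediate early genes were lower in CD161+ cells: 4 of 17 lower, 2 higher and 5 lower adjusted over the list alone (adjusted p = 5.84e-05), among them IER3 (−2.06 ± 0.34) and NR4A1 (−1.18 ± 0.21). Naive T cell genes were lower: 5 of 12 lower, 5 lower adjusted over the list alone (adjusted p = 5.95e-06), among them PECAM1 (−2.53 ± 0.38). Innate-like genes gave 3 of 12 higher, 5 higher adjusted over the list alone (adjusted p = 7.84e-06). Without KLRB1, 2 of 11 were higher (adjusted p = 6.61e-04). Follicular helper genes had 1 of 6 higher, 2 higher adjusted over the list alone (adjusted p = 5.26e-04). Cell division genes had 1 of 13 higher, 4 higher adjusted over the list alone (adjusted p = 5.26e-04). Interferon genes had 2 of 14 higher, 4 higher adjusted over the list alone (adjusted p = 3.16e-04). Ribosome biogenesis gave 0 of 12 past the threshold, 1 lower adjusted over the list alone and 3 lower at an unadjusted p under 0.05 (adjusted p = 4.74e-04, 0.102 with an estimated correlation, fry adjusted p = 0.0480). HLA class II had 0 of 7 past the threshold, 0 adjusted over the list alone and 1 higher at an unadjusted p under 0.05 (adjusted p = 0.0145, 0.234 with an estimated correlation, fry adjusted p = 0.151). Signs of median, mean and test differed for tissue repair factors and NF-kB targets, which did not pass. PECAM1 had a lower mean of 4.27, near background. The cell division list lost its call without dim probe sets (adjusted p = 0.478).

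Limma called 469 genes here, 294 higher and 175 lower. A fit of these 6 arrays alone gave 736 and array weights gave 1124. Removing donors gave 161, 213 and 177 without donor 1, 2 and 3, and removing single arrays 273 and 281 without activated CD161+ replicate 1 and 3 and 282 and 296 without activated naive replicate 1 and 3.

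Activated memory and naive Tregs were compared in the same way. HPGD, which encodes the enzyme that breaks down prostaglandin E2, was 14.4-fold higher in memory cells (3.84 ± 0.28, adjusted p = 3.00e-06). CCR6 (3.55 ± 0.33, adjusted p = 2.47e-05) and IL13 (3.50 ± 0.67, adjusted p = 0.0098) were higher too. IL5 (3.42 ± 0.60, adjusted p = 0.0051) and TNIP3 (3.38 ± 0.38, adjusted p = 9.33e-05) were also higher. CLDN1 (−2.80 ± 0.24, adjusted p = 1.59e-05), PTK2 (−2.77 ± 0.27, adjusted p = 3.15e-05) and SERPINE2 (−2.58 ± 0.44, adjusted p = 0.0043) were lower. HOMER1 (−2.42 ± 0.36, adjusted p = 0.0017) and the receptor feedback inhibitor gene ERRFI1 (−2.19 ± 0.21, adjusted p = 2.47e-05) were lower as well. KLRB1 (1.55 ± 0.53, adjusted p = 0.231), FOXP3 (0.07 ± 0.19, adjusted p = 0.999), IL2RA (0.55 ± 0.22, adjusted p = 0.406) and CTLA4 (0.65 ± 0.22, adjusted p = 0.242) did not pass. IL5 and PTK2 had lower means of 3.34 and 4.10, near background.

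Activated memory Tregs stood above naive Tregs in memory and effector genes: 10 of 16 higher, 13 higher adjusted over the list alone (adjusted p = 1.29e-29). The type 17 list gave 7 of 16 higher, 9 higher adjusted over the list alone (adjusted p = 1.43e-21), with BATF higher by 2.51 ± 0.40. Gut homing receptors showed 5 of 8 higher, 6 higher adjusted over the list alone (adjusted p = 1.82e-15). Skin homing receptors had 3 of 5 higher, 3 higher adjusted over the list alone (adjusted p = 2.12e-07). Type 2 genes had 5 of 9 higher, 6 higher adjusted over the list alone (adjusted p = 5.16e-14). Suppressive mediators showed 4 of 14 higher, 8 higher adjusted over the list alone (adjusted p = 1.96e-11), with IL10 higher by 2.74 ± 0.43. Induced cytokines showed 6 of 22 higher, 9 higher adjusted over the list alone (adjusted p = 4.71e-10), with CCL20 higher by 2.31 ± 0.41. Treg core genes showed 2 of 15 higher, 6 higher adjusted over the list alone (adjusted p = 1.22e-07). Type 1 genes had 2 of 9 higher, 5 higher adjusted over the list alone (adjusted p = 1.19e-07). Costimulatory receptors had 1 of 13 higher, 7 higher adjusted over the list alone (adjusted p = 2.12e-07). Immediate early genes went both ways: 1 of 17 higher and 4 lower, 1 higher and 6 lower adjusted over the list alone (adjusted p = 1.01e-05), with NR4A1 at −1.11 ± 0.21 and FOSB at −1.16 ± 0.23. Naive T cell genes showed 2 of 12 lower, 4 lower adjusted over the list alone (adjusted p = 0.0178, 0.182 with an estimated correlation). Innate-like genes had 2 of 12 higher, 3 higher adjusted over the list alone (adjusted p = 0.0092, 0.106 with an estimated correlation). Follicular helper genes had 1 of 6 higher, 2 higher adjusted over the list alone (adjusted p = 0.0282, 0.0703 with an estimated correlation). Interferon genes had 2 of 14 higher, 2 higher adjusted over the list alone (adjusted p = 8.86e-04, 0.0651 with an estimated correlation). HLA class II gave 0 of 7 past the threshold, 0 adjusted over the list alone and 3 higher at an unadjusted p under 0.05 (adjusted p = 1.56e-04, 0.0703 with an estimated correlation, fry adjusted p = 0.0514). Ribosome biogenesis gave 0 of 12 past the threshold, 1 lower adjusted over the list alone and 5 lower at an unadjusted p under 0.05 (adjusted p = 9.42e-05, 0.0703 with an estimated correlation, fry adjusted p = 0.0290). Cell division had 0 of 13 past the threshold, 1 higher adjusted over the list alone and 2 higher at an unadjusted p under 0.05 (adjusted p = 0.0282, 0.194 with an estimated correlation, fry adjusted p = 0.177). Signs of median, mean and test differed for tissue repair, cytotoxicity, glycolysis and natural killer cell lists, which did not pass. Follicular helper and cell division lists lost calls without dim probe sets (adjusted p = 0.0836 and 0.845).

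The activated memory and naive groups differed in 287 genes, 196 higher and 91 lower. The count was 529 in a fit of these 6 arrays and 772 with array weights. Donors left out gave 71, 98 and 85 without donor 1, 2 and 3, and single arrays 171, 185 and 149 without activated memory replicate 1, 2 and 3 and 175 and 182 without activated naive replicate 1 and 3.

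Activation of CD161+ Tregs was followed by comparing activated with fresh cells, without a shift, since centring moved the all-gene median of −0.12 only to −0.10. IL13, which encodes a cytokine of type 2 responses, rose (6.01 ± 0.67, adjusted p = 1.53e-05). The chemokine genes CCL20 (5.83 ± 0.41, adjusted p = 1.29e-07) and CCL4 (5.67 ± 0.68, adjusted p = 3.38e-05) and the early transcription factor genes EGR1 (5.61 ± 0.25, adjusted p = 1.35e-09) and EGR3 (5.45 ± 0.27, adjusted p = 2.24e-09) rose too. Histone genes H3C1 (−3.81 ± 0.29, adjusted p = 2.58e-07), H2BC14 (−3.16 ± 0.42, adjusted p = 7.94e-05), H1-3 (−3.08 ± 0.25, adjusted p = 5.47e-07) and H2BC10 (−2.84 ± 0.30, adjusted p = 9.29e-06) fell, as did BIRC5, which encodes survivin (−3.00 ± 0.66, adjusted p = 0.0051). Histone genes have near-identical copies, so it is uncertain which member each probe set measured. IL2RA (2.41 ± 0.22, adjusted p = 1.56e-06) and the activation marker gene CD69 (2.93 ± 0.25, adjusted p = 8.16e-07) rose. IL2 (5.34 ± 0.41, adjusted p = 2.88e-07) and IL10 (5.07 ± 0.43, adjusted p = 6.69e-07) rose as well. FOXP3 was at 0.51 ± 0.19, adjusted p = 0.0791, and 0.0315 with the donor as a block. IL13, CCL4, H3C1 and IL2 had lower means of 4.21, 3.54, 4.30 and 3.06, near background.

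Treg core genes rose in CD161+ cells: 10 of 15 rising, 14 rising adjusted over the list alone (adjusted p = 6.55e-17), led by TNFRSF9 (4.67 ± 0.24) and LRRC32 (3.08 ± 0.31). NF-kB targets rose: 11 of 12 rising, 11 rising adjusted over the list alone (adjusted p = 2.63e-22), among them NFKBIZ (2.32 ± 0.16). Immediate early genes rose: 13 of 17 rising and 1 falling, 14 rising and 1 falling adjusted over the list alone (adjusted p = 1.26e-19), among them NR4A3 (5.10 ± 0.33). Induced cytokines gave 16 of 22 rising, 18 rising adjusted over the list alone (adjusted p = 5.81e-25), with IFNG rising by 5.35 ± 0.54 and IL21 by 5.08 ± 0.34. Type 17 genes gave 11 of 16 rising, 12 rising adjusted over the list alone (adjusted p = 1.97e-14), with IRF4 rising by 4.88 ± 0.23 and IL17A by 4.27 ± 0.40. Costimulatory receptors gave 7 of 13 rising and 1 falling, 10 rising and 1 falling adjusted over the list alone (adjusted p = 8.68e-10), with CD274 rising by 3.99 ± 0.60 and CD27 at −1.61 ± 0.21. Ribosome biogenesis gave 8 of 12 rising, 8 rising adjusted over the list alone (adjusted p = 2.89e-08). Type 2 genes gave 4 of 9 rising, 4 rising adjusted over the list alone (adjusted p = 7.95e-05, 0.0905 with an estimated correlation). Type 1 genes had 4 of 9 rising and 1 falling, 4 rising and 2 falling adjusted over the list alone (adjusted p = 0.0040, 0.139 with an estimated correlation). Suppressive mediators had 4 of 14 rising and 1 falling, 4 rising and 1 falling adjusted over the list alone (adjusted p = 0.0031, 0.0708 with an estimated correlation). Follicular helper genes gave 2 of 6 rising, 2 rising adjusted over the list alone (adjusted p = 0.0193, 0.0708 with an estimated correlation). Tissue repair factors gave 3 of 12 rising, 3 rising adjusted over the list alone (adjusted p = 0.0249, 0.244 with an estimated correlation). Cell division genes gave 5 of 13 falling, 8 falling adjusted over the list alone (adjusted p = 0.0069, 0.139 with an estimated correlation), with CCNB1 at −1.17 ± 0.23. Interferon genes gave 1 of 14 rising and 6 falling, 1 rising and 7 falling adjusted over the list alone (adjusted p = 0.0216, 0.199 with an estimated correlation), with IFI6 at −1.26 ± 0.20 and IFIT3 rising by 1.37 ± 0.23. CCR9 of the gut homing list fell by 1.85 ± 0.30 while CCR6 rose by 1.14 ± 0.33. Glycolysis genes split, with 4 of 15 rising and 5 falling, 5 rising and 5 falling adjusted over the list alone (adjusted p = 0.538), with PFKFB3 rising by 3.21 ± 0.28 and PFKL at −1.11 ± 0.15. CD79B, a B cell marker, fell by 0.85 ± 0.24 (list adjusted p = 0.538). Median, mean and test differed in sign for memory and effector, glycolysis, heat shock and CD8 T cell lists. IL21 and CCNB1 had lower means of 3.85 and 4.23, near background. Tissue repair factors, type 1, type 2, follicular helper and interferon response lists lost calls without dim probe sets (adjusted p = 0.0546, 0.0546, 0.0678, 0.0546 and 0.0851).

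In CD161+ Tregs 2674 genes changed on activation, 1352 up and 1322 down, or 843 and 1033 with array background as a covariate. The count was 4309 with array weights, 1741, 1136 and 1477 without donor 1, 2 and 3, and 1750 without activated CD161+ replicate 2.

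Memory Tregs were activated in the same way. Changes are relative to the all-gene median of −0.19 (−0.03 after centring, −0.004 without dim probe sets), while p-values test them unshifted. The shift may overcorrect bright genes and puts the changes off the CD161+ scale. NAMPT, which encodes the rate-limiting enzyme of NAD salvage (5.84 ± 0.25, adjusted p = 3.19e-10), IRF4 (5.82 ± 0.23, adjusted p = 3.04e-10) and CCL20 (5.65 ± 0.41, adjusted p = 1.84e-07) rose most. TNFRSF9, which encodes the receptor CD137 (5.61 ± 0.24, adjusted p = 3.19e-10) and EGR3 (5.59 ± 0.27, adjusted p = 1.58e-09) came next. H1-3 (−3.71 ± 0.25, adjusted p = 3.23e-08), H2AC15 (−3.69 ± 0.22, adjusted p = 1.29e-08), H2BC14 (−3.56 ± 0.42, adjusted p = 1.21e-05), H3C1 (−3.40 ± 0.29, adjusted p = 3.10e-07) and H2AC8 (−3.31 ± 0.21, adjusted p = 2.02e-08), all histone genes with near-identical copies, fell most. IL2RA (2.51 ± 0.22, adjusted p = 2.09e-06), CD69 (3.46 ± 0.25, adjusted p = 1.99e-07), IL2 (5.49 ± 0.41, adjusted p = 1.96e-07), IL10 (4.55 ± 0.43, adjusted p = 2.91e-06) and FOXP3 (0.97 ± 0.19, adjusted p = 0.0072) rose. CCL20, IL2 and IL10 had lower means of 4.41, 3.10 and 4.17, near background, with changes of 5.47, 5.30 and 4.36 before the shift.

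In memory cells Treg core genes rose: 13 of 15 rising, 14 rising adjusted over the list alone (adjusted p = 1.71e-14), with LRRC32 rising by 4.14 ± 0.31. Immediate early genes, EGR1 (5.48 ± 0.25) among them, gave 13 of 17 rising and 1 falling, 14 rising and 1 falling adjusted over the list alone (adjusted p = 1.43e-15). NF-kB targets had 11 of 12 rising, 11 rising adjusted over the list alone (adjusted p = 7.18e-17), with NFKB1 rising by 3.47 ± 0.21. Induced cytokines gave 15 of 22 rising, 15 rising adjusted over the list alone (adjusted p = 1.28e-14), with IFNG rising by 5.10 ± 0.54. Type 17 genes gave 10 of 16 rising, 10 rising adjusted over the list alone (adjusted p = 6.52e-09), with IL1R1 rising by 4.22 ± 0.37. Costimulatory receptors gave 8 of 13 rising and 1 falling, 8 rising and 1 falling adjusted over the list alone (adjusted p = 9.30e-07). Ribosome biogenesis gave 10 of 12 rising, 10 rising adjusted over the list alone (adjusted p = 4.81e-10). Follicular helper genes gave 3 of 6 rising, 3 rising adjusted over the list alone (adjusted p = 0.0028). Type 1 genes gave 4 of 9 rising and 1 falling, 5 rising and 2 falling adjusted over the list alone (adjusted p = 0.0049, 0.162 with an estimated correlation). Type 2 genes had 5 of 9 rising, 6 rising adjusted over the list alone (adjusted p = 7.33e-05, 0.0888 with an estimated correlation). Suppressive mediators had 4 of 14 rising and 1 falling, 5 rising and 1 falling adjusted over the list alone (adjusted p = 0.0050, 0.0866 with an estimated correlation). Glycolysis gave 6 of 15 rising and 3 falling, 7 rising and 3 falling adjusted over the list alone (adjusted p = 0.0411, 0.335 with an estimated correlation), and adjusted p = 0.0525 with the donor as a block. Signs of median and test differed for memory and effector, innate-like and monocyte lists, which did not pass. HBB, a red cell marker, fell (−1.52 ± 0.48, adjusted p = 0.0181), the 1 call among 6 platelet and red cell markers (list adjusted p = 0.378). Olfactory receptor genes, the background measure, had a median change of −0.26 before that shift, against −0.19 for all genes. IL1R1 and HBB had lower means of 4.55 and 3.74, near background, with changes of 4.03 and −1.71 before the shift. Type 1 and glycolysis lists lost calls without dim probe sets (adjusted p = 0.127 and 0.355).

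Activation changed 4362 genes in memory Tregs, 2109 up and 2253 down, or 2453 and 849 after median centring. With array background as a covariate, a term that runs with activation, 583 genes passed, 352 up and 231 down, and 40 of 87 named calls ended. The count was 3275, 1056 and 2106 without donor 1, 2 and 3, and 2544 and 2189 without activated memory replicate 2 and 3.

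Activation was also compared in naive Tregs. Changes are relative to the all-gene median of −0.26 (−0.12 after centring, −0.07 without dim probe sets), with the same limits of this shift. P-values test unshifted changes. EGR1 (6.33 ± 0.25, adjusted p = 1.89e-10), TNFRSF9 (6.27 ± 0.24, adjusted p = 1.49e-10) and EGR3 (6.24 ± 0.27, adjusted p = 3.79e-10) rose most. IL2 (6.06 ± 0.41, adjusted p = 3.61e-08) and the amino acid transporter gene SLC7A5 (5.92 ± 0.27, adjusted p = 4.79e-10) came next. H3C1 (−4.17 ± 0.29, adjusted p = 1.56e-08), H2BC7 (−3.89 ± 0.28, adjusted p = 2.94e-08), H1-3 (−3.59 ± 0.25, adjusted p = 1.90e-08), H2AC15 (−3.50 ± 0.22, adjusted p = 8.33e-09) and H2BC10 (−3.48 ± 0.30, adjusted p = 1.51e-07) fell most, again with near-identical copies. IL2RA (2.69 ± 0.22, adjusted p = 4.47e-07), CD69 (4.21 ± 0.25, adjusted p = 1.42e-08), and FOXP3 (0.96 ± 0.19, adjusted p = 0.0072) rose. IL10 rose by 1.24 ± 0.43 before that shift, adjusted p = 0.0267. TNFRSF9, IL2 and IL10 had lower means of 4.21, 3.09 and 4.55, near background, with changes of 6.01, 5.80 and 1.24 before the shift.

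Naive cells raised their Treg core genes: 12 of 15 rising, 13 rising adjusted over the list alone (adjusted p = 1.38e-09), with IKZF4 rising by 3.32 ± 0.27. Immediate early genes showed 14 of 17 rising and 1 falling, 14 rising and 1 falling adjusted over the list alone (adjusted p = 7.20e-12). NF-kB targets had 10 of 12 rising, 11 rising adjusted over the list alone (adjusted p = 2.73e-11), with REL rising by 4.77 ± 0.29. Ribosome biogenesis showed 9 of 12 rising, 9 rising adjusted over the list alone (adjusted p = 1.31e-07), with WDR43 rising by 3.35 ± 0.22. Costimulatory receptors showed 7 of 13 rising and 2 falling, 7 rising and 2 falling adjusted over the list alone (adjusted p = 0.0023). Induced cytokines showed 9 of 22 rising, 9 rising adjusted over the list alone (adjusted p = 1.87e-05, 0.240 with an estimated correlation), with TNF rising by 4.39 ± 0.27. Type 17 genes showed 5 of 16 rising and 1 falling, 5 rising and 1 falling adjusted over the list alone (adjusted p = 0.0456, 0.386 with an estimated correlation), with AHR rising by 4.94 ± 0.35. Type 1 genes had 4 of 9 rising, 4 rising adjusted over the list alone (adjusted p = 0.0290, 0.369 with an estimated correlation). Heat shock genes went both ways: 4 of 7 rising and 2 falling, 4 rising and 2 falling adjusted over the list alone (adjusted p = 0.148), with HSPH1 at 3.96 ± 0.37 and HSPB1 at −1.13 ± 0.22. Platelet and red cell markers gave 3 of 6 falling, 3 falling adjusted over the list alone (adjusted p = 0.339, fry adjusted p = 0.0189), with PF4 at −0.71 ± 0.30. The B cell marker CD79B fell (−0.93 ± 0.24) and the NK cell marker SH2D1B was called lower (−0.25 ± 0.16). For skin homing, mean and test differed in sign. Olfactory receptor genes had a median change of −0.32 before that shift, against −0.26 for all genes. SH2D1B lay near background in both states (lower mean 2.68), so −0.51 unshifted is no bound. Type 17, type 1 and costimulatory receptors lists lost calls without dim probe sets (adjusted p = 0.260, 0.263 and 0.0514).

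In naive Tregs 8237 genes changed on activation, 3229 up and 5008 down, or 3501 and 2805 after median centring. The count was 4823 in a fit of these 6 arrays, 869 with the background covariate and 3053 without the highest-background pair. The last fit has 1 fresh naive array, assumed to vary like the other groups. Of these 2249, 340 and 1287 went down, fewer than went up, and the covariate ended or turned 47 of 87 named calls. Without donor 1, 2 and 3 it was 4677, 4178 and 6859.

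**Figure D4:**
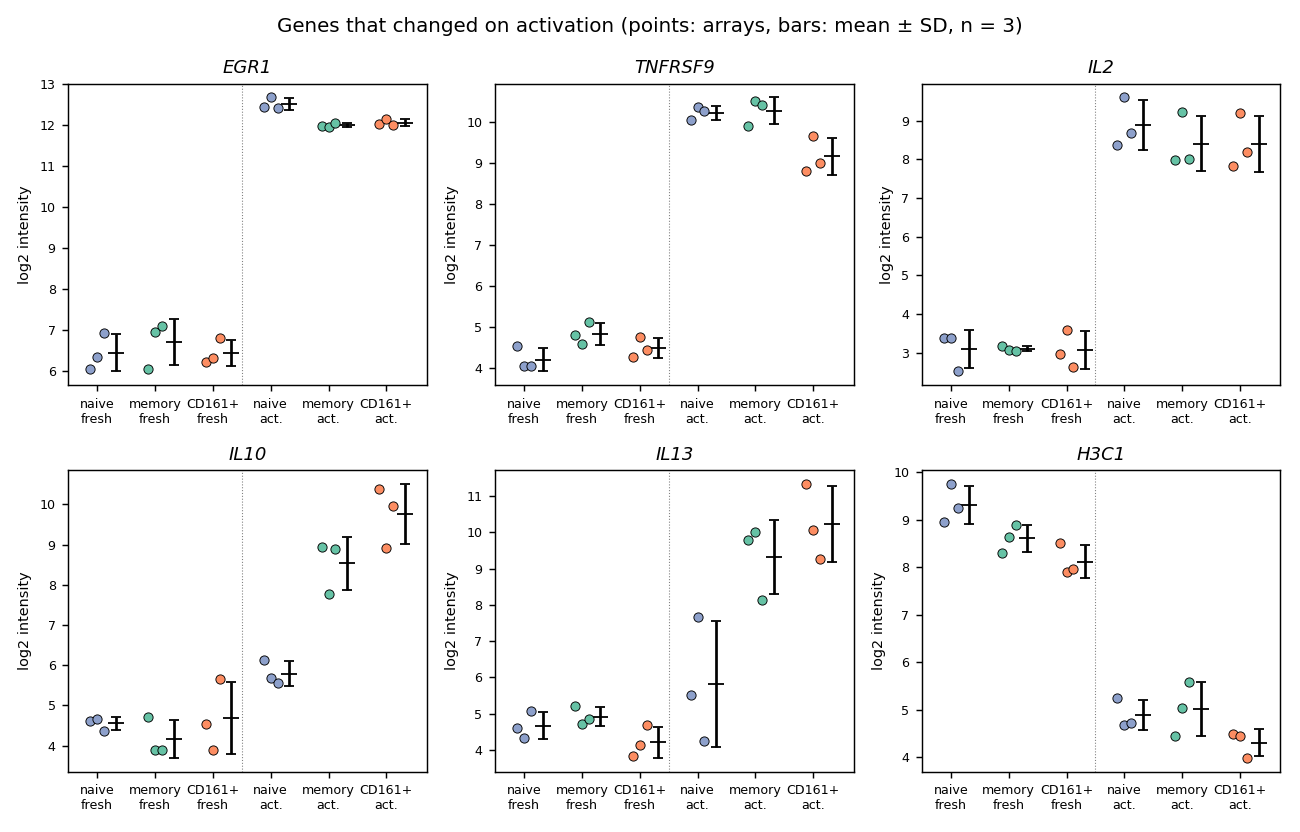
Log2 intensity (y axis) of 6 genes in the 6 groups (x axis), with 1 point per array and bars for the mean ± SD (n = 3). IL10 reached a mean of 9.75 in activated CD161+, 8.53 in activated memory and 5.79 in activated naive Tregs.

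Whether the response to activation differed between CD161+ and memory Tregs was tested as a difference of changes, given relative to the all-gene median of 0.03 (−0.11 after median centring). OR51G2, an olfactory receptor gene near background (1.39 ± 0.22, adjusted p = 0.0456), and CGAS, which encodes a cytosolic DNA sensor (−1.89 ± 0.28, adjusted p = 0.0456), passed, with adjusted p = 0.0827 and 0.0827 with the donor as a block. IL10 (0.67 ± 0.60, adjusted p = 0.746), IL2RA (0.06 ± 0.31, adjusted p = 0.944) and CD69 (−0.37 ± 0.36, adjusted p = 0.790) did not. Neither did IL2 (0.01 ± 0.57, adjusted p = 0.991) or FOXP3 (−0.30 ± 0.26, adjusted p = 0.772). Induced cytokines leaned toward a more upward response in CD161+ cells: 0 of 22 past the threshold, 0 adjusted over the list alone and 6 higher at an unadjusted p under 0.05 (adjusted p = 0.0021, 0.898 with an estimated correlation, fry adjusted p = 0.701). IL17A of that list was at 1.84 ± 0.57, adjusted p = 0.501 and IL21 at 1.48 ± 0.48, adjusted p = 0.502.

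In limma 1486 genes had an unadjusted p under 0.05 and 2, OR51G2 and CGAS, were called. Of the calls, 1 changed more upward in CD161+ and 1 in memory cells (1 and 3 after median centring). The count was 0 with the donor as a block, 0 after quantile normalization, 0 without dim probe sets and 0 with the background covariate (unadjusted 1720, 1111, 908 and 1342). It was 0, 0 and 0 without donor 1, 2 and 3, and single arrays gave 1, 0 and 0 without activated CD161+ replicate 1, 2 and 3, 8, 0 and 0 without fresh CD161+ replicate 1, 2 and 3, 0 without activated memory replicate 1, 2 or 3 and 0, 0 and 12 without fresh memory replicate 1, 2 and 3, with unadjusted counts between 746 and 1496 where it was 0.

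The response of memory Tregs was compared with that of naive Tregs as a difference of changes, without a shift, since the all-gene median was 0.04. TNIP3, an NF-kB inhibitor gene (3.43 ± 0.54, adjusted p = 0.0262), SPINK2 (1.90 ± 0.33, adjusted p = 0.0316) and the costimulatory ligand gene CD80 (1.87 ± 0.32, adjusted p = 0.0316) changed more upward in memory cells. P2RX4 (1.72 ± 0.30, adjusted p = 0.0316) and ZNF671 (1.65 ± 0.30, adjusted p = 0.0361) did so too. CLDN1 (−2.62 ± 0.34, adjusted p = 0.0038), ERRFI1 (−2.48 ± 0.30, adjusted p = 0.0038) and NRIP1 (−2.38 ± 0.39, adjusted p = 0.0316) changed more upward in naive cells. MAP3K2 (−2.22 ± 0.39, adjusted p = 0.0316) and PTK2 (−2.20 ± 0.38, adjusted p = 0.0316) did so too. IL10 was at 3.12 ± 0.60, adjusted p = 0.0504, and 0.0179 with the donor as a block. IL2RA (−0.11 ± 0.31, adjusted p = 0.944) and CD69 (−0.68 ± 0.36, adjusted p = 0.506) did not pass. Neither did IL2 (−0.50 ± 0.57, adjusted p = 0.836) or FOXP3 (0.09 ± 0.26, adjusted p = 0.947). Type 17 genes leaned toward a more upward response in memory cells: 0 of 16 past the threshold, 6 higher and 1 lower adjusted over the list alone and 8 higher and 1 lower at an unadjusted p under 0.05 (adjusted p = 2.91e-04, 0.342 with an estimated correlation, fry adjusted p = 0.0850). Induced cytokines gave 0 of 22 past the threshold, 6 higher adjusted over the list alone and 9 higher at an unadjusted p under 0.05 (adjusted p = 0.0019, 0.712 with an estimated correlation, fry adjusted p = 0.376). Type 2 genes had 0 of 9 past the threshold, 2 higher adjusted over the list alone and 3 higher and 1 lower at an unadjusted p under 0.05 (adjusted p = 0.0300, 0.727 with an estimated correlation, fry adjusted p = 0.388), with IL5 at 4.02 ± 0.85, adjusted p = 0.0817. Immediate early genes leaned the other way: 0 of 17 past the threshold, 0 adjusted over the list alone and 1 higher and 3 lower at an unadjusted p under 0.05 (adjusted p = 0.0157, 0.443 with an estimated correlation, fry adjusted p = 0.197). Signs of median, mean and test differed, near 0, for naive T cell, HLA class II, innate-like, glycolysis and interferon lists. Type 2 and immediate early lists lost calls without dim probe sets (adjusted p = 0.273 and 0.113).

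Of 26 genes called, 9 changed more upward in memory and 17 more upward in naive cells. The count was 4 when only these 4 groups were fitted, 42 with the donor as a block, 263 with array weights and 7 without the highest-background pair (1 fresh naive array left). It was 0, 1 and 100 without donor 1, 2 and 3 (unadjusted 1236 for the count of 0), and single arrays gave 3, 6 and 8 without activated memory replicate 1, 2 and 3, 12 and 13 without fresh memory replicate 1 and 2, 5 without activated naive replicate 1 or 3 and 17, 10 and 793 without fresh naive replicate 1, 2 and 3.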

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

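The tests of the spread between activated arrays, of the histone genes against background and of the cell division list, and the fits with a background covariate or without the highest-background arrays, were chosen only after the result was seen.

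A difference between the responses of 2 populations, tested as such, marked 12 named genes, each with the same sign in 3 of 3 donors. Between CD161+ and memory Tregs these were OR51G2 (1.42 ± 0.22, adjusted p = 0.0456) and CGAS (−1.86 ± 0.28, adjusted p = 0.0456), here before the shift by the all-gene median. Between memory and naive Tregs the difference was 3.43 ± 0.54 for TNIP3, adjusted p = 0.0262, 1.65 ± 0.30 for ZNF671, adjusted p = 0.0361, and 1.90 ± 0.33 for SPINK2, 1.87 ± 0.32 for CD80 and 1.72 ± 0.30 for P2RX4, each with adjusted p = 0.0316. It was −2.62 ± 0.34 for CLDN1 and −2.48 ± 0.30 for ERRFI1, each with adjusted p = 0.0038, and −2.38 ± 0.39 for NRIP1, −2.22 ± 0.39 for MAP3K2 and −2.20 ± 0.38 for PTK2, each with adjusted p = 0.0316.

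For the 2 genes called between the responses of CD161+ and memory Tregs, 4 of 100 drawn splits gave as many, and the highest other gave 5. The other drawn splits mix real groups, which widens their spread, and most kept a donor pair together, so this cannot exclude chance. Among the 14 that parted all donor pairs, as the real one did, the highest other gave 2, as many as the real one. For the 26 genes between memory and naive Tregs, 11 of 100 drawn splits gave as many and the highest other gave 1414, so chance cannot be excluded. That split also parted all donor pairs (1 of 16 such), and the highest of those that kept a pair gave 356. Why that split gave so many more genes than the real one was not tested.

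In the other 9 comparisons 6 arrays make 10 splits, too few for a share under 0.05, and only the real one gave as many genes. Fresh CD161+ and memory, CD161+ and naive, and memory and naive Tregs had 116, 2677 and 1675 genes against 3, 259 and 602 in the highest other split. In the last 2 that split kept a donor pair together, and the highest other of the 4 that parted all pairs gave 0 and 23. Activated cells, in the same order, had 4, 469 and 287, each against 0. Activation of CD161+, memory and naive Tregs had 2674, 4362 and 8237 against 0, 1 and 0. Other splits mix the real groups, which widens their spread, so low counts there decide nothing.

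Activation gave the most falling genes in naive Tregs, 5008 against 2253 in memory and 1322 in CD161+ Tregs, an order that turned with background as a covariate (340, 231 and 1033). Without the highest-background pair the falls were 1287, 3302 and 1756, but that leaves 1 fresh naive array, and lost precision was not told apart from background. Higher background on fresh naive arrays is 1 candidate explanation, with a median change of −0.32 in olfactory receptor genes against −0.26 in all genes. Naive Tregs kept the most falls after quantile normalization (3924, 1628 and 1355) and median centring (2805, 849 and 1200). The olfactory median there was still −0.09 and −0.19, so this cannot decide. A single array also counts, since without fresh naive replicate 1 the falls were 3223 in naive and 2939 in memory Tregs, a ratio of 1.10, against ratios of 1.71 and 2.11 without replicate 2 and 3. The covariate runs with activation, so a larger response of naive Tregs stays open.

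CD161+ and memory Tregs differed in 116 genes when fresh and 4 after activation, but in 1 and 2 when only the 6 arrays of each comparison were fitted. Larger spread between activated arrays is argued against, since their median residual SD per gene was 0.727 of that of fresh arrays. The main fit gave all groups 1 spread, while median SDs were 0.26 and 0.20 in fresh and 0.17 and 0.16 in activated memory and CD161+ Tregs. A shared spread tends to make p-values too small for fresh and too large for activated arrays. The counts of 116 and 4 are thus not on the same footing. The 100 genes picked on the fresh arrays of the other donors differed in the held-out donor by 0.90, 1.03 and 0.61 when fresh and by 0.34, 0.13 and 0.12 when activated, a mean ratio of 0.23, so a fading of the fresh differences is a candidate explanation. Picked on activated arrays instead, genes differed by 0.76, 0.59 and 0.82 when activated and by 0.25, 0.48 and 0.49 when fresh, so each state also had differences of its own. The count of 116 itself ran from 3 to 691 with arrays left out, which keeps the size of the contrast open.

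Histone genes fell on activation in all 3 populations, 46, 46 and 50 of 55 in CD161+, memory and naive Tregs, with medians of −1.53, −2.20 and −2.33. Background of the fresh arrays is argued against, since the smallest gap to the olfactory receptor genes was −1.43, and the medians were −1.46, −1.95 and −1.95 with background as a covariate, −1.51, −2.05 and −2.19 after median centring and −1.56, −2.35 and −2.47 after quantile normalization. Loss of short RNAs without a poly(A) tail stays open. The 195 snoRNA and small nuclear RNA genes (medians 0.09, −0.16, −0.21) may not track histones. Fewer dividing cells cannot be told apart, since the cell division list had a highest median of −0.11, in memory Tregs, where 6 of its 13 members lay near background and the other 7 went both ways, from −0.82 to 0.29. A response of the histone genes to activation stays open as a hypothesis.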

How the results depend on the processing

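The background covariate, the fit without the highest-background pair of arrays, both from the fresh naive group, and the lists without KLRB1 were chosen after seeing the data, and all other tests here were planned. The cause was not tested unless stated, and fits of the contrast's groups alone, without a donor or without an array have fewer samples. The fit without that pair leaves 1 fresh naive array, assumed to vary like the other groups, so its counts with naive cells also carry lost precision. Of simulated 2-fold changes, 64% were recovered in fresh and 66% in activated CD161+ against memory Tregs. It was 62% for activation in memory Tregs and 24% for the difference of responses, with false calls of 6.29%, 6.16%, 4.90% and 5.61%. Differences from a level near background are lower bounds in size. Median SDs per gene between donors were 0.32, 0.26 and 0.20 in fresh naive, memory and CD161+ Tregs and 0.18, 0.17 and 0.16 after activation. Whether simulated rates hold with such spreads was not tested.

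Fits of the contrast's groups alone gave 1 gene between fresh CD161+ and memory Tregs (limma, unadjusted 2283), 584 against naive and 58 between memory and naive Tregs. In activated cells they gave 2, 736 and 529, for activation of naive Tregs 4823, and for the differences of responses 1 and 4. The donor block gave 189 between fresh and 2 between activated CD161+ and memory Tregs, and 0 (unadjusted 1720) and 42 for the differences of responses. It also ended the call of CYP26B1 in activation of naive Tregs (−0.45, adjusted p = 0.0501), and changed no other call of a named gene or list than those given beside the results. The background covariate gave 195, 577 and 950 in the fresh comparisons, 583 and 869 for activation of memory and naive Tregs, and 0 (unadjusted 1342) for CD161+ against memory responses. Without the highest-background pair the fresh comparisons gave 555, 635 and 247, activation of naive Tregs 3053, and the differences of responses 5 and 7.

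Array weights gave 45, 1124 and 772 in the activated comparisons, 4309 for activation of CD161+ Tregs, and 5 and 263 for the differences of responses. For the CD161+ against memory responses, quantile normalization gave 0 (unadjusted 1111), median centring 4, and trend with robust 1. Without dim probe sets that count was 0 (unadjusted 908), with fewer genes tested, and between activated CD161+ and memory Tregs 2. An adjusted p under 0.1 gave 445, 4148 and 2691 in the fresh comparisons, 435 between activated memory and naive Tregs and 54 for their responses.

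With a donor or a single array left out, the fresh counts ranged from 3 to 691 (CD161+ and memory), 527 to 4573 (CD161+ and naive) and 222 to 3351 (memory and naive). The activated counts ranged from 0 to 5, 161 to 348 and 71 to 232. Activation ranged from 1136 to 2265 in CD161+, 1056 to 4099 in memory and 4178 to 9537 in naive Tregs. The differences of responses ranged from 0 to 12 and 0 to 793. Where limma gave 0, unadjusted counts were 362 to 574 between activated CD161+ and memory Tregs, 746 to 1496 for their responses and 1236 for memory against naive responses. An added 1.5-fold minimum and the mean of probe sets moved no count by over 1.5 times.

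Sign changes came with the covariate in activation of naive Tregs, to −0.38 for IL12RB2, 0.14 for ZBTB16, 0.28 for ALDH1A2, 0.22 for CDC20, 0.39 for PF4 and 0.13 for CA1, none of them past the threshold then. The cell division list between activated memory and naive Tregs turned to a median of −0.0767 without dim probe sets. Of 482 values of named genes, 346 kept direction and side of the threshold with the covariate, 404 without the highest-background pair, 458 after quantile normalization, 471 with the block, and 351, 324 and 372 without donor 1, 2 and 3. The rest kept direction and lost the call, except the 6 sign changes above and 1, 1, 5 and 1 that gained it with the covariate, without that pair, with the block and without donor 3. Of 114 list calls, 55 held with an estimated correlation, 112 with the donor block and 88 without dim probe sets. Without KLRB1, 5 of 6 list calls held.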

Other observations

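The overlaps between contrasts were chosen as tests only after the results were seen.

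Much of the response to activation was shared. A total of 987 genes rose and 610 fell in each of the 3 populations. Between memory and naive Tregs 1806 rises and 1648 falls were shared, against 371.0 and 614.7 expected if the calls were independent, with 6 genes called in opposite directions and a correlation of changes across genes of 0.856. CD161+ and memory Tregs shared 1057 rises and 667 falls, where 155.4 and 162.3 were expected, with a correlation of 0.776. CD161+ and naive Tregs shared 1181 rises and 1005 falls, where 237.9 and 360.7 were expected, with 0.756. Genes are not independent, and the contrasts share donors, spread and a fall in background, which the expected counts ignore. No overlap was tested.

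KLRB1 and HRH4, 2 genes, were higher in CD161+ than in memory Tregs in both states (0.0153 expected), and the correlation of the differences across genes was 0.0978. Between CD161+ and naive Tregs 188 genes were higher and 50 lower in both states (29.2 and 8.12 expected), with a correlation of 0.322. Between memory and naive Tregs these were 116 and 27 (11.6 and 2.91 expected), with 0.418.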
